A study of Mus musculus with 4 samples.

How the data were processed

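Polyadenylated RNA of mouse embryonic stem cells (ESCs) was sequenced in 4 libraries, 2 labelled wild type (WT) and 2 labelled Naa10 knockout (Naa10-KO). Per the labels' protocols, the lines came from blastocysts of a cross between C57BL/6 females carrying the knockout and JF1 males, and the WT lines were littermates. JF1 is an inbred strain of Japanese origin that is distant from C57BL/6, so the cells are hybrids of distant mouse strains. The cells grew in serum-free medium with inhibitors of Mek and Gsk3 and with LIF, for 5 passages on irradiated fibroblast feeders and 5 passages without them. Poly-dT beads selected the RNA, sonication broke it into fragments of about 200 bp, random hexamers primed the cDNA, and an Illumina HiSeq 2000 read the libraries. No label states a strand-specific protocol, so whether reads of a gene and of its antisense partner were told apart is not known.

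The values are RPKM (reads per kilobase of transcript, scaled to the mapped reads of the library), per the file headers, in 1 deposited table per library. Per the submitters' processing notes, the genome build was mm9 and the tools included Cufflinks and bedtools, with no versions; the aligner and the gene annotation are not given in the sources used here. Each table held the same 14099 named rows with 13974 distinct symbols. Of these rows, 404 joined several symbols, as Cufflinks does for loci that share transcripts, and 221 rows belonged to 96 repeated symbols. Rows were kept apart as deposited. A further 270 rows were named only for small RNAs, which a poly-dT library of fragments this long measures poorly, and 323 rows were listed at exactly 0 in at least 1 library. Genes that every cell uses were among them. Eef1a1, a translation elongation factor named after its values were seen, was listed at 0 in Naa10-KO replicate 2 alone. An exact 0 was therefore treated as a possible failed estimate. Rows at 0 are given as values per library, without a fold. The lowest maximum over the libraries was 0.270 RPKM, so genes below that level are not analysed here.

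Fragment counts were not used here, and RPKM hide the depth. Low values of rows up to 75 nt long moved in steps, and the step size gave the relative depth. It was 1 for WT replicate 1, 1.02 for WT replicate 2, 1.46 for Naa10-KO replicate 1 and 1.68 for Naa10-KO replicate 2. Each was the most common ratio to WT replicate 1 over classes of row length. WT replicate 2 had it in 10 of 15 classes, Naa10-KO replicate 1 in 8 of 13 and Naa10-KO replicate 2 in 5 of 11. The totals came from a second search for steps, over genes with a single transcript longer than 500 nt. It assumed fragments of 200 nt and put the totals at an estimated 50600000, 51800000, 73400000 and 85300000 fragments. The fragments per gene given below rest on the same assumption. The replicates of each group were compared before they were averaged. Over the 451 genes with 100 to 500 estimated fragments, the mean chi-square per gene was 1.84 between the WT libraries, where sampling noise alone gives about 1, and 27.7 over 428 genes between the Naa10-KO libraries. The WT mean was 1.30 at 20 to 100 fragments and 2.04 at 500 to 2000. The WT libraries thus lay close to sampling noise, and both were kept. Whether they differed by more than sampling noise stays open, because error of the RPKM estimates adds to these values. Design text and titles call all 4 libraries biological replicates, with no word on whether they came from separate lines or separate cultures of a line, and p-values measure the spread between these libraries only.

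Differences were tested with limma 3.58.1 in R 4.3.3 on log2(RPKM + 1), with a mean-variance trend, two-sided, on the 11912 rows at 1 RPKM or more in at least 2 of the 4 libraries. Benjamini-Hochberg adjusted p under 0.05 counted as past the threshold. Fold changes on this scale understate the change of low genes. With 2 libraries per group, the fit had 2 residual degrees of freedom and borrowed 1.94 more across genes. Gene lists were tested with camera at a preset correlation of 0.01 between genes, with adjustment over the 29 lists that had at least 5 tested rows, out of 31 lists fixed in advance. Joined rows entered a list once if any of their symbols was on it. The same lists were tested with a correlation estimated from the data and with fry. Tables were handled in Python 3.11.15 with pandas 2.3.3. The RefSeq gene table at hand belongs to another assembly (GRCm38.p6) than the deposited values, so it served only to assign rows to chromosomes, which it did for 14065 rows, and to find genes whose spans overlap. No coordinates are given.

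Before the data were examined, the lists, the tests, most alternatives and the rule for named genes were fixed. The rule named Naa10, 14 further genes of DNA methylation, imprinting, pluripotency and X inactivation, the 8 rows with the largest change in each direction among those past the threshold with both Naa10-KO libraries on one side of both WT libraries, and members of the lists, up to 3 past the threshold for lists past theirs or otherwise the member with the smallest unadjusted p. Because the rule filled its top 8 places with rows listed at 0, it was applied again after seeing the data to the rows without a 0 that are not small RNAs, called well-measured rows here. Other genes chosen after their values were seen are marked as such, and a gene that the rule took for a list is not reported here. The alternatives changed the pseudocount, the filter, the scaling, the variance model, the threshold and the libraries used, added the replicate number as a block, and left out genes of the sex chromosomes. Alternatives chosen after seeing the data left out rows at 0, small RNA rows or both, counted identical rows once, weighted each group by its spread, crossed the replicate numbers, or left joined rows out of the lists.

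The test was tried on simulated data made for the comparison of 2 Naa10-KO with 2 WT libraries, with the means and spreads of 11659 well-measured rows, of which 200 were changed. It recovered 2% of rows changed by 0.5 on the log2 scale, 64% of those changed by 1, 96% of those changed by 2 and 100% of those changed by 4, with 50 rows per size. Of its 141 calls, 10 were false. Of 20 simulated lists of 25 rows shifted by 0.5, camera at the preset correlation recovered 20, and it called 0 of 20 lists that were not shifted. Camera with an estimated correlation and fry also recovered 20 of 20 and called 0 of the others. The simulated genes were independent of each other, which real genes are not. Each simulated row also had a single spread in both groups, already borrowed in part across genes. The real groups differed in spread, so the recovered shares may not hold for them, and the real comparison over these 11659 rows gave 0 calls.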

Results

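Gene expression was profiled in mouse ESCs labelled Naa10-KO and in WT ESCs of the same cross, with 2 libraries per genotype. Naa10 is the catalytic subunit of NatA, the complex that acetylates the N-termini of many proteins as they leave the ribosome. The series title asks about Naa10 in DNA methylation and genomic imprinting, the marking of a gene by the parent that passed it on. The tables gave 14099 named rows in RPKM. The estimated depth was 50600000 and 51800000 fragments for the WT libraries and 73400000 and 85300000 for the Naa10-KO libraries. The WT libraries lay close to each other, with a median absolute difference of 0.05 on the log2 scale. Naa10-KO replicates 1 and 2 differed by 0.24, about as much as either differed from WT (0.20 to 0.28).

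Naa10 was measured in a row joined with its X-chromosome neighbour Renbp, so its own level cannot be separated, and which part of the gene was deleted is not given in the sources used here. The row stood at 105 and 106 RPKM in the WT libraries and at 28.9 and 34.4 RPKM in the Naa10-KO libraries, or 27.5% and 32.7% of the WT mean. It fell by 1.71 on the log2 scale (SE 0.11, limma adjusted p = 0.0342). Both libraries labelled Naa10-KO thus lay below both libraries labelled WT. The call rested on the multiple-testing adjustment, with an adjusted p of 0.0820 when rows listed at 0 and small RNA rows were left out. The row stayed lower in Naa10-KO with any library left out. Without a WT library it did not pass, but the lone WT library was then assumed to vary like the Naa10-KO pair. Such a fit does not show that the call rested on either WT library. Among the 14 tested rows of the list of N-terminal acetyltransferase subunits, the Naa10 row fell and 13 did not pass. Naa11, a retrogene copy of Naa10 that can share reads with it, had 8.61 and 8.58 RPKM in WT and 4.43 and 6.10 RPKM in Naa10-KO (adjusted p = 0.164); it was named after its values were seen.

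**Figure D1:**
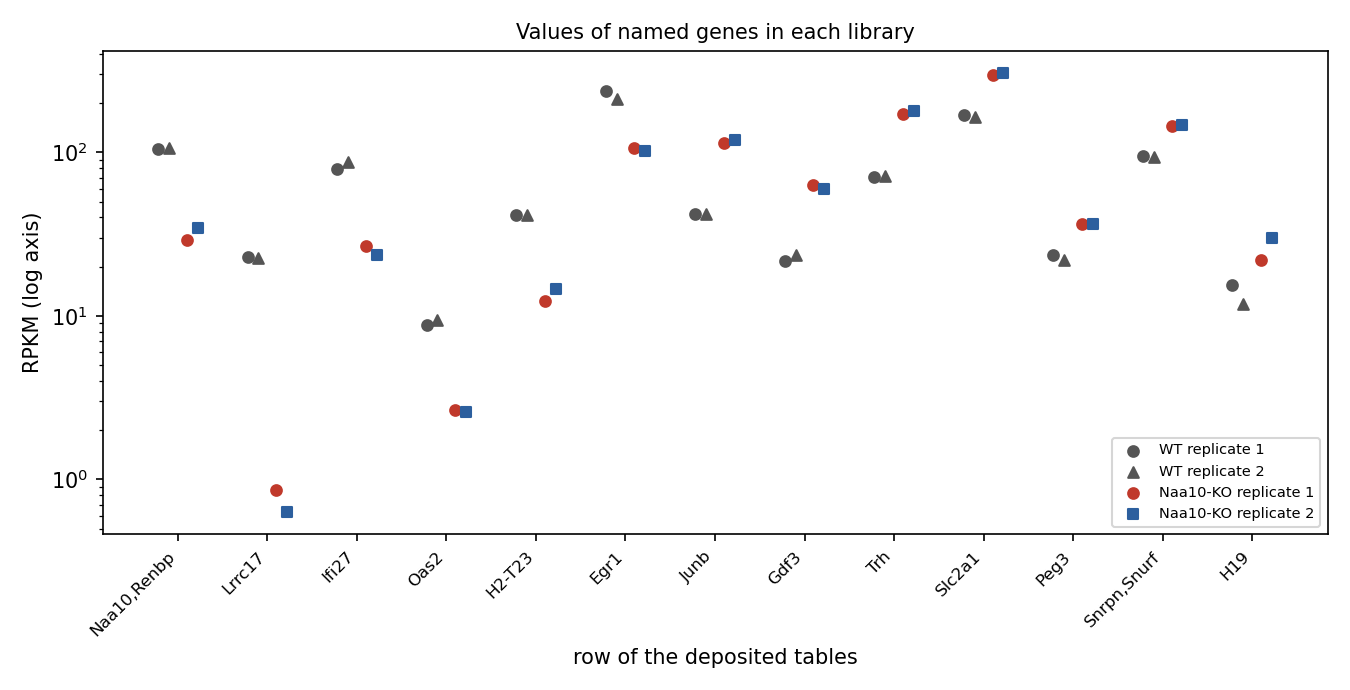
RPKM of named rows in each library on a log axis, with WT libraries in grey and Naa10-KO replicates 1 and 2 in red and blue; each point is a library. The joined row of Naa10 and Renbp stood near 105 RPKM in WT and at 28.9 and 34.4 RPKM in Naa10-KO, and Lrrc17 lay below 1 RPKM in both Naa10-KO libraries.

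Between Naa10-KO and WT, 91 of the 11912 tested rows passed the threshold, 26 higher and 65 lower in Naa10-KO. Only 38 of them were well-measured rows, 11 of which rose and 27 of which fell. A further 34 were small RNA rows, including 10 identical rows of Rn4.5s. The remaining 19 were rows of other genes listed at 0 in both libraries of a group. None of the 38 well-measured rows passed when rows at 0 and small RNA rows were left out: limma then gave 0 calls over 11659 rows, with a smallest adjusted p of 0.0591, while 2624 rows had an unadjusted p under 0.05 against 583 expected with no effect and an equal spread in both groups, which these groups did not have. With a library left out, the lone library of its group is assumed to vary like the other pair. The median absolute log2 difference was 0.05 within the WT pair and 0.24 within the Naa10-KO pair. The count then followed the pair that gave the spread, with few calls without a WT library and many without a Naa10-KO library. These fits thus do not show which library carried a call.

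Among the well-measured rows that rose was Junb, an AP-1 transcription factor, at 41.9 ± 0.141 RPKM in WT and 117 ± 3.23 RPKM in Naa10-KO (SD, n = 2 each), or 2.79-fold (log2 change 1.46, SE 0.07, limma adjusted p = 0.0156). Trh, the precursor of thyrotropin-releasing hormone, rose 2.44-fold to 174 ± 5.10 RPKM (n = 2). Gdf3, a TGF-beta family ligand made by pluripotent cells, rose 2.71-fold to 61.6 ± 2.75 RPKM (n = 2). Igfbp4, which binds insulin-like growth factors, rose 3.03-fold, the transcription factor gene Bhlhe40 2.35-fold, Zfp428 2.31-fold and the glucose transporter gene Slc2a1 1.80-fold. The joined row of 4933408J17Rik and Ccdc38 rose 4.61-fold from a low level of 1.31 ± 0.0840 RPKM (n = 2). Adjusted p for these 8 rows ran from 0.0156 for Junb to 0.0451 for Bhlhe40.

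Lrrc17, which encodes a secreted leucine-rich repeat protein, fell most among the well-measured rows, from 22.8 ± 0.127 to 0.746 ± 0.166 RPKM (SD, n = 2 each; limma log2 change -3.77, SE 0.12, adjusted p = 0.00607). Akap5, a scaffold for protein kinase A, fell from 5.70 ± 0.0255 to 0.270 ± 0.0160 RPKM (n = 2 each; log2 change -2.40, adjusted p = 0.0153). The interferon-induced gene Ifi27 fell to 0.303 of its WT level, Pbld1 to 0.299, the non-classical MHC class I gene H2-T23 to 0.325 and Gm5531 to 0.235. 2700099C18Rik went from 2.38 ± 0.206 to 0.110 ± 0.0112 RPKM (n = 2 each). Adjusted p for Ifi27, Pbld1, H2-T23, 2700099C18Rik and Gm5531 lay between 0.0335 and 0.0470.

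The rows with the largest fitted changes were listed at 0 in a whole group. Plekhj1 was listed at 39.5 and 40.0 RPKM in WT and at 0 in both Naa10-KO libraries, and Kdelr3, a receptor that returns proteins to the endoplasmic reticulum, at 34.2 and 33.7 RPKM in WT and at 0 in both Naa10-KO libraries. The other way round, Ssr4, a subunit of the translocon-associated complex that lies near Naa10 on the X chromosome, was listed at 0 in both WT libraries and at 42.6 and 49.6 RPKM in Naa10-KO. Rfc4, a subunit of the clamp loader of DNA replication, was listed at 0 in both WT libraries and at 31.7 and 35.7 RPKM in Naa10-KO, and 2900097C17Rik at 0 in WT and at 105 and 158 RPKM in Naa10-KO. The other 11 rows that the rule took were small RNA rows at 0 in a group. In Naa10-KO these were Mir6988, Mir6927, Mir7005, Mir6931, Mir6955 and Mir6943, and in WT they were Mir688, Mir7051, Mir3072, Mir6913 and Snord85. Of the 21 tested rows near Naa10 on the X chromosome, Ssr4 was counted as risen and the Naa10 row as fallen, and 19 did not pass (camera adjusted p = 0.0735).

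Paternally expressed imprinted genes were higher in Naa10-KO as a group, and maternally expressed ones were not. Of 24 tested rows of paternally expressed genes, 19 were higher, with a median log2 difference of 0.50 (camera adjusted p = 7.68e-05; adjusted p = 0.405 with an estimated correlation). None of the 24 passed over all genes tested, and 8 rose when adjusted over the list alone. The joined row of Snrpn and Snurf, genes of the Prader-Willi region, had 94.0 ± 0.706 RPKM in WT and 145 ± 1.63 RPKM in Naa10-KO (SD, n = 2 each; limma adjusted p = 0.0628). Peg3, a zinc finger gene, had 22.8 ± 1.15 and 36.2 ± 0.0219 RPKM (n = 2 each; log2 difference 0.64, adjusted p = 0.0878). Named after their values were seen, Peg10 had 49.7 and 42.9 RPKM in WT against 190 and 132 RPKM in Naa10-KO, and Mest 28.5 and 27.6 against 52.4 and 46.4 RPKM. The list's median log2 difference from WT was 0.51 in Naa10-KO replicate 1 and 0.31 in replicate 2.

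Of 28 tested rows of maternally expressed imprinted genes, 14 were higher and 14 lower, and 0 passed over all genes or adjusted over the list alone (camera adjusted p = 0.450, median log2 difference 0.00). The list's median lay on opposite sides of WT, at 0.21 in Naa10-KO replicate 1 and -0.13 in replicate 2. The paternally expressed list lay above the maternally expressed one by 0.50 at the median, and camera between the lists gave p = 0.00939, or p = 0.117 with an estimated correlation. The joined row of AF357359 and Rian, a noncoding RNA of the Dlk1-Dio3 region, had 11.4 and 11.3 RPKM in WT and 41.0 and 26.8 RPKM in Naa10-KO (adjusted p = 0.103). Its neighbour Meg3, in a joined row, had 4.52 and 4.80 RPKM in WT and 7.67 and 4.56 RPKM in Naa10-KO (adjusted p = 0.519), with a log2 difference of -0.026 without Naa10-KO replicate 1. H19 had 13.6 ± 2.52 RPKM in WT and 25.9 ± 5.67 RPKM in Naa10-KO (n = 2 each; log2 difference 0.88, limma adjusted p = 0.150). The paternally expressed Igf2, which shares its imprinting control region with H19, had 13.5 and 6.01 RPKM in WT and 6.22 and 5.83 RPKM in Naa10-KO (limma adjusted p = 0.468). Its lower mean in Naa10-KO came from WT replicate 1, and its log2 difference without that library was 0.0036. Over both imprinted lists, limma called 0 of 52 rows over all genes, 11 with adjustment over these lists alone and 18 at an unadjusted p under 0.05. Low p-values were common among rows at large, with 2634 of all 11912 tested rows at an unadjusted limma p under 0.05. With a Naa10-KO library left out, the other is assumed to vary like the WT libraries, so counts are not given for those fits.

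The DNA methylation machinery was not past the threshold as a list or in any of its 29 tested rows (camera adjusted p = 0.450, fry adjusted p = 0.0911). Small changes are not excluded, as the simulated test recovered 2% of rows changed by 0.5. Both Naa10-KO libraries lay above both WT libraries in 10 of the 29 rows and below both in 17. Of all tested rows, 59.3% lay apart in this way. Dnmt1, the maintenance methyltransferase, had 76.5 ± 0.932 RPKM in WT and 71.9 ± 2.95 RPKM in Naa10-KO (SD, n = 2 each; log2 difference -0.09, limma adjusted p = 0.499), and its partner Uhrf1 had a log2 difference of -0.16 (adjusted p = 0.369). The de novo methyltransferase genes lay apart, with log2 differences of -0.37 for Dnmt3a (adjusted p = 0.198) and 0.35 for Dnmt3b (adjusted p = 0.258). Their cofactor gene Dnmt3l had 0.39 (adjusted p = 0.277), and Zfp57, which protects imprints, had -0.25 (adjusted p = 0.234). Ctcfl, a germline relative of CTCF, had the smallest p of the list, at 1.74 ± 0.197 and 0.812 ± 0.115 RPKM (n = 2 each; adjusted p = 0.137).

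Germline genes that DNA methylation silences in somatic cells were lower in Naa10-KO as a group. Of 30 tested rows, 24 were lower (median log2 difference -0.43, camera adjusted p = 0.00393; adjusted p = 0.405 with an estimated correlation). None passed over all genes; 10 fell and 1 rose when adjusted over the list alone. Sycp3, a protein of the meiotic chromosome axis, had 9.74 ± 0.144 RPKM in WT and 3.64 ± 0.699 RPKM in Naa10-KO (n = 2 each; limma adjusted p = 0.0863). Markers of the 2-cell-like state, a rare state of ESC cultures, were also lower, in 8 of 9 tested rows (median -0.83, camera adjusted p = 0.00149; adjusted p = 0.469 with an estimated correlation). Of these, 0 passed over all genes and 6 fell when adjusted over the list alone, all 6 from the Zscan4 cluster of near-identical copies, whose reads cannot be assigned with certainty. Zscan4e had 1.75 ± 0.00850 RPKM in WT and 0.476 ± 0.185 RPKM in Naa10-KO (n = 2 each; adjusted p = 0.104).

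Interferon response genes were lower in both Naa10-KO libraries. Of 25 tested rows 20 were lower, with a median log2 difference of -0.52 (camera adjusted p = 0.000337; adjusted p = 0.405 with an estimated correlation). Ifi27 and Oas2 fell over all genes, and 10 fell when adjusted over the list alone. Ifi27 went from 83.0 ± 6.36 to 25.2 ± 2.08 RPKM, and Oas2, an enzyme that senses double-stranded RNA, from 9.12 ± 0.424 to 2.63 ± 0.0582 RPKM (SD, n = 2 each; limma adjusted p = 0.0335 and 0.0414). Stat2, a transcription factor of the pathway that was named after its values were seen, had 8.98 and 8.51 RPKM in WT and 2.32 and 3.38 RPKM in Naa10-KO (adjusted p = 0.0902). Psme2, an interferon-inducible activator of the proteasome, fell to 0.519 of WT (adjusted p = 0.0418); the other 40 of 41 tested proteasome rows did not pass (camera adjusted p = 0.112).

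**Figure D2:**
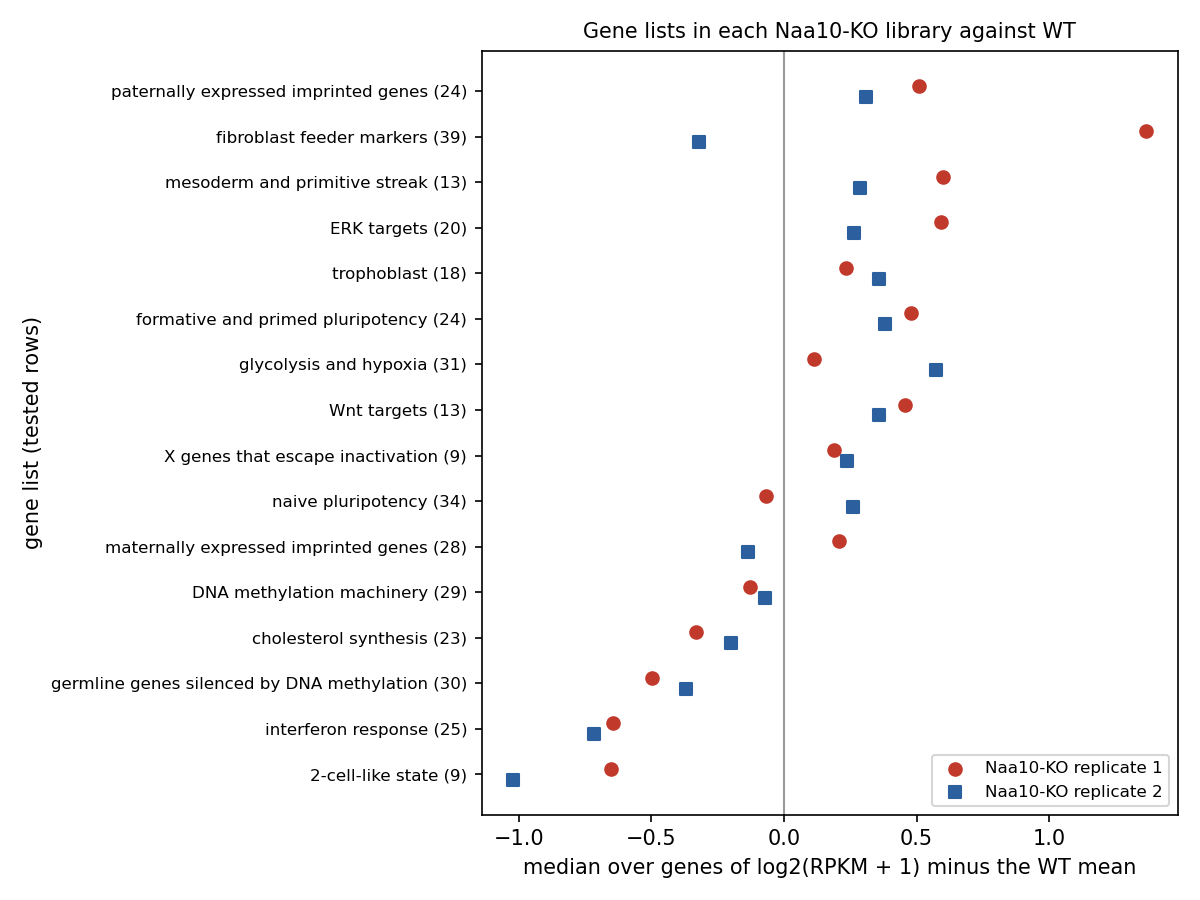
Median over the tested rows of each gene list of log2(RPKM + 1) minus the WT mean, for Naa10-KO replicate 1 (red circles) and replicate 2 (blue squares); the lists past the camera threshold are drawn with the maternally expressed imprinted genes and the DNA methylation machinery. Fibroblast feeder markers lay at 1.36 in replicate 1 and at -0.32 in replicate 2, and interferon response genes at -0.64 and -0.72.

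Genes of formative and primed pluripotency, the states that follow the naive one, were higher in 21 of 24 tested rows (median log2 difference 0.40, camera adjusted p = 0.000337; adjusted p = 0.405 with an estimated correlation). None passed over all genes, and 2 rose when adjusted over the list alone. Foxd3, a transcription factor of this transition, had 4.89 ± 0.250 RPKM in WT and 11.3 ± 0.563 RPKM in Naa10-KO (SD, n = 2 each; limma adjusted p = 0.0654). The naive pluripotency list passed too (19 of 34 rows higher, median 0.07, camera adjusted p = 0.00586; adjusted p = 0.508 with an estimated correlation), with Gdf3 the one gene that rose over all genes and 4 that rose when adjusted over the list alone. Its call ended without Naa10-KO replicate 2 (adjusted p = 0.712), and its median was -0.07 in replicate 1 and 0.26 in replicate 2. Pou5f1 had 812 ± 4.91 and 948 ± 32.8 RPKM (n = 2 each; log2 difference 0.22, adjusted p = 0.177). The Naa10-KO libraries lay on opposite sides of WT for Nanog, at 258 and 253 RPKM in WT and 175 and 312 RPKM in Naa10-KO (adjusted p = 0.814). Sox2 did likewise, at 215 and 220 RPKM in WT and 155 and 258 RPKM in Naa10-KO (adjusted p = 0.806). The log2 differences of Nanog and Sox2 were 0.29 and 0.25 without Naa10-KO replicate 1 and -0.55 and -0.48 without replicate 2.

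ERK targets were higher as a group although the medium held a Mek inhibitor, in 16 of 20 tested rows (median log2 difference 0.47, camera adjusted p = 0.000337; adjusted p = 0.405 with an estimated correlation). Members moved both ways, as Junb rose while Egr1, an immediate early gene, fell from 238 and 211 RPKM in WT to 106 and 102 RPKM in Naa10-KO (log2 change -1.10, limma adjusted p = 0.0431). When adjusted over the list alone, 8 rose and 2 fell. The list's median was 0.59 in Naa10-KO replicate 1, the library in which fibroblast feeder markers were high, and 0.26 in replicate 2. Wnt targets had a median of 0.34 over 13 tested rows, 8 of them higher (camera adjusted p = 0.0167; adjusted p = 0.405 with an estimated correlation); 0 passed over all genes, and 6 rose and 1 fell when adjusted over the list alone. Lef1, a transcription factor of Wnt signalling, had 12.7 ± 0.0986 RPKM in WT and 35.9 ± 6.24 RPKM in Naa10-KO (n = 2 each; adjusted p = 0.0662). The Wnt call ended without Naa10-KO replicate 1 (adjusted p = 0.0648) and without replicate 2 (adjusted p = 0.0847).

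Of 4 lists of lineage genes, 2 passed, both as higher. Mesoderm and primitive streak genes were higher in 9 of 13 tested rows (median 0.48, camera adjusted p = 0.0232; adjusted p = 0.469 with an estimated correlation), and trophoblast genes in 13 of 18 (median 0.41, camera adjusted p = 0.00586; adjusted p = 0.405 with an estimated correlation). Gata2, a transcription factor on both lists, had 1.57 ± 0.0320 RPKM in WT and 4.10 ± 0.378 RPKM in Naa10-KO (SD, n = 2 each; limma adjusted p = 0.0863). None passed over all genes, while adjusted over the list alone 2 mesoderm genes rose and 1 fell, and 1 trophoblast gene rose. The mesoderm call ended without Naa10-KO replicate 1 (adjusted p = 0.0963), the library in which fibroblast markers were high, and the trophoblast call ended when only rows with a mean of 5 RPKM or more were tested (adjusted p = 0.0756). Endoderm and neuroectoderm genes did not pass (camera adjusted p = 0.0588 and 0.0806), and their medians were 0.36 and 0.44 in Naa10-KO replicate 1 against 0.08 and 0.02 in replicate 2.

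Genes of glycolysis and hypoxia were higher in 24 of 31 tested rows (median log2 difference 0.35, camera adjusted p = 0.00044; adjusted p = 0.508 with an estimated correlation). Slc2a1 was the member that rose over all genes, from 167 ± 4.45 to 300.4 ± 7.26 RPKM (SD, n = 2 each; limma adjusted p = 0.0414), and 2 rose when adjusted over the list alone. The list's median was 0.11 in Naa10-KO replicate 1 and 0.57 in replicate 2. Genes of cholesterol synthesis were lower in 19 of 23 tested rows (median -0.34, camera adjusted p = 0.00586; adjusted p = 0.405 with an estimated correlation), with 0 past over all genes and 4 that fell when adjusted over the list alone. The cholesterol call ended without Naa10-KO replicate 1 (adjusted p = 0.0648).

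Fibroblast feeder markers were high in Naa10-KO replicate 1 alone. Of 39 tested markers, 34 were higher there than in both WT libraries and 24 were more than 2-fold above the WT mean, whereas in Naa10-KO replicate 2 none exceeded 2-fold and 31 were lower than in both WT libraries. The median log2 ratio to WT was 1.36 in replicate 1 and -0.32 in replicate 2. Named after their values were seen, the actin-binding protein gene Tagln had 19.7 and 20.2 RPKM in WT, 192 RPKM in Naa10-KO replicate 1 and 19.6 RPKM in replicate 2. The surface receptor gene Cd44 had 4.20 and 4.91 RPKM in WT, 46.2 RPKM in replicate 1 and 4.05 RPKM in replicate 2. Fn1, fibronectin, had the smallest p, at 189 ± 0.659 RPKM in WT and 242 ± 16.1 RPKM in Naa10-KO (SD, n = 2 each; limma adjusted p = 0.136). As a list the markers passed as higher (camera adjusted p = 0.0253; adjusted p = 0.754 with an estimated correlation), with 0 of 39 past over all genes or adjusted over the list alone. Without Naa10-KO replicate 1 the direction turned (adjusted p = 0.00134, lower), and the call ended with quantile normalization (adjusted p = 0.0572) and with median-ratio scaling (adjusted p = 0.0972).

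Genes of the X chromosome that escape inactivation were higher in 8 of 9 tested rows (median log2 difference 0.29, camera adjusted p = 0.0271; adjusted p = 0.405 with an estimated correlation, and fry adjusted p = 0.0250). Kdm5c, a histone demethylase, had 17.1 ± 0.0127 RPKM in WT and 23.9 ± 3.04 RPKM in Naa10-KO (SD, n = 2 each; limma adjusted p = 0.158), and 0 of 9 passed over all genes or adjusted over the list alone. One of the 9, Bgn, is also a fibroblast marker. The list's median was 0.19 in Naa10-KO replicate 1 and 0.24 in replicate 2, where 297 X-linked genes as a whole had medians of 0.03 and 0.25, and whether the list differed from other X-linked genes was not tested. The call ended without Naa10-KO replicate 1 (adjusted p = 0.102) and with the filter at a mean of 5 RPKM (adjusted p = 0.0642). Xist, the RNA that silences an X chromosome, stood at 0.506 and 0.531 RPKM in WT and 0.542 and 0.184 RPKM in Naa10-KO, below the level tested, as did the whole lists of the X inactivation centre and of Y chromosome genes.

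The other lists did not pass camera. Rfc4, at 0 in WT, was the 1 row of 30 in DNA replication and S phase past the gene threshold (camera adjusted p = 0.405). No row passed over all genes in heat shock and chaperones (30 rows, camera adjusted p = 0.0735), oxidative phosphorylation (42 rows, 0.0809), p53 targets (29 rows, 0.0877), the integrated stress response (25 rows, 0.193), G2 and M phase of the cell cycle (30 rows, 0.205), cytosolic ribosomal proteins (77 rows, 0.455) and the unfolded protein response (25 rows, 0.550). The acetyltransferase subunits had a camera adjusted p of 0.0962. With a correlation estimated from the data, 0 of the 14 lists past camera's threshold kept their calls, and fry, which asks whether a list's genes move one way, called 1, the X genes that escape inactivation.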

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

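The alternatives that left out rows at 0 or small RNA rows, weighted groups, crossed replicate numbers, or left joined rows out of the lists were chosen after seeing the data. The count of 91 called rows moved to 325 at an adjusted p under 0.1, to 40 without a filter on low values (of which 40 were among the 91), to 26 without small RNA rows, to 0 without rows listed at 0 and to 0 without either kind. In that last setting limma gave 2624 rows an unadjusted p under 0.05. Weighting each group by its spread in addition gave 86 calls, 35 of them among the 38 well-measured ones. The weight alone, with all tested rows kept, gave 82 calls, 20 of them among the 38. Leaving out each library in turn gave 6 to 7177 calls, 6 without WT replicate 1, 7 without WT replicate 2, 5158 without Naa10-KO replicate 1 and 7177 without Naa10-KO replicate 2. A lone library is then assumed to vary like the other group, and the WT libraries vary little. The Naa10 row kept its log2 change of -1.71 but not its call without rows at 0 (adjusted p = 0.0629) and without either kind (adjusted p = 0.0820); over the libraries left out, its log2 change ran from -1.83 to -1.59. The 0 imprinted rows became 2 with both kinds of rows left out and a weight per group, and the count also moved when libraries were left out. The 14 called lists became 0 with an estimated correlation and 1 with fry; under the remaining alternatives the count lay between 11 and 19. Fibroblast feeder markers turned lower without Naa10-KO replicate 1 (adjusted p = 0.00134) and were higher without any other library (adjusted p from 1.57e-14 to 0.00639). Of single genes, the log2 difference of Igf2 ran from -1.04 without WT replicate 2 to 0.0036 without WT replicate 1. Without Naa10-KO replicate 1 that of Meg3 turned to -0.026, of Sox2 to 0.25 and of Nanog to 0.29; without Naa10-KO replicate 2 these were 0.62, -0.48 and -0.55. Xist gave no values, nor did the list of the 2-cell-like state without WT replicate 1 or 2, or that list and the mesoderm list with the filter at a mean of 5 RPKM, where fewer than 5 of their rows were tested. Beyond the settings named, the cause was not tested. The depth ran from 50600000 to 85300000 estimated fragments, and rows near the floor of 1 RPKM rest on the fewest.

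The samples share only a number: replicate 1 minus replicate 2 differences in WT and Naa10-KO correlated at -0.21 across tested rows. With the replicate number as a block, 44 rows, 1 imprinted row and 16 lists were called. The Naa10 row kept its call, as did 7 of the 38 well-measured rows in all; Gdf3, H2-T23, Oas2, Slc2a1, Psme2 and Egr1 were among those that did not. With crossed numbers, the counts were 133 rows, 2 imprinted rows and 18 lists.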

Other observations

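Of the tests in this part, those of feeder cells, loss of Naa10, depth and a library split in parts were chosen after the result was seen. Transcripts of the Y chromosome were low in all 4 libraries. Ddx3y had 0.754 and 0.992 RPKM in WT and 0.341 and 0.215 RPKM in Naa10-KO, while its X-linked partner Ddx3x had 176 and 186 RPKM in WT and 199 and 173 RPKM in Naa10-KO. Eif2s3y had 0.482 and 0.705 RPKM in WT and 0.0816 and 0.0223 RPKM in Naa10-KO. Uty had 0.463 and 0.448 RPKM in WT and 0.230 and 0.115 RPKM in Naa10-KO. The labels give the cross as females carrying the knockout with JF1 males and do not give the sex of the lines. A daughter of such a cross inherits an intact Naa10 on her father's X chromosome. A line without any intact copy would thus have come from a male embryo, unless the father's X chromosome was lost. Such a loss was not tested. With the Y transcripts this low, and the joined row of Naa10 and Renbp at 27.5% and 32.7% of WT, whether the Naa10-KO lines are full knockouts stays open and was not tested. Over 297 X-linked genes the median log2 ratio to WT was 0.03 in Naa10-KO replicate 1 and 0.25 in replicate 2, against -0.07 and -0.02 over 9064 autosomal genes.

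Rows at 0 in a whole group stood beside high values in the other group. Among genes other than small RNAs with 10 RPKM or more in both libraries of the other group, 9 were listed at 0, 4 of them in WT and 5 in Naa10-KO, and none lay above 0 but under 2% of the other group. Genes switched off by genotype would be likely to leave such small residues. The count of 0 graded rows argues against that explanation for the 9 rows at 0. The count depends on the 2% limit, as Lrrc17, over 10 RPKM in WT, lay just above it at 0.0327 of its WT level. Failed or reassigned estimates where genes overlap remain open: the odds ratio for overlapping another RefSeq gene span was 1.30, over 8 rows with a known span against 5639 rows never at 0 (Fisher's exact test, two-sided, p = 0.734), and 8 rows are too few to decide.

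The fibroblast signal in Naa10-KO replicate 1 was uneven, as in Vim and Col1a1, which were named after their values were seen. Vim had 118 and 128 RPKM in WT, 386 RPKM in replicate 1 and 137 RPKM in replicate 2. Col1a1 had 14.3 and 14.9, 36.9 and 8.47 RPKM in the same order. More of the same feeder cells as in the other libraries would raise most those markers with the least signal from the stem cells themselves. The 4 markers under 0.3 of WT in Naa10-KO replicate 2, Lum, Postn, Col3a1 and Dcn, reached at most 1.60-fold of WT in replicate 1, against a median of 2.84-fold over all 39 markers, which argues against more of the same cells as the whole explanation. With the limit at 0.5 the median was 1.76-fold over 10 markers against 3.54-fold over the other 29, although Col5a2 at 4.48-fold and Twist2 at 3.40-fold lay above the median of all. For loss of Naa10, replicate 2 has the same label but a median log2 ratio of -0.32, so the label alone did not bring the signal. The outcome of this test followed from how the signal was picked, as high in replicate 1 alone. Feeders in another state, or stem cells that differentiated in that culture, may both account for the signal and were not tested.

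The WT libraries were closer to each other than the Naa10-KO libraries, at a median absolute log2 difference of 0.05 against 0.24. Deeper sequencing of WT is argued against by the relative depth, at least 1.46 in the Naa10-KO libraries against 1 in WT replicate 1. Leaving out the markers and the rows more than 0.5 above WT in Naa10-KO replicate 1 did not close the gap. Over the 10494 other rows, the Naa10-KO pair still differed 4.30 times as much as the WT pair. Rows raised by the fibroblast signal thus did not account for the gap alone. Rows lower than WT in replicate 1, such as Nanog and Sox2, were kept, so falls that came with that signal are not excluded. A WT library deposited in 2 parts would give a mean chi-square per gene near 1 and a median near 0.455; the means were 1.30, 1.84 and 2.04 in rising classes of estimated fragments, with medians of 0.526, 0.680 and 0.773, and because error of the RPKM estimates adds to such values, this stays open. WT libraries from one culture, Naa10-KO lines from different embryos, and more variable cells without Naa10 stay open and were not tested.

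The 4 libraries can be split into 2 and 2 in 3 ways, too few for a share under 0.05. The real split gave 91 calls and the highest of the others 6, so 1 split gave as many. Over well-measured rows alone, each of the 3 splits gave 0 calls with limma, and an unadjusted p under 0.05 was found in 2624 rows for the real split and in 16 and 40 for the others, whose groups each mix both genotypes.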
